A study of Mus musculus with 15 samples.

How the data were processed

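Polyadenylated RNA was measured by sequencing in 15 libraries of mouse embryonic stem (ES) cells, strain C57BL/6N per the labels. The libraries fall into 6 groups, made of wild type (WT) and Mettl5-/- (knockout, KO) lines in each of 3 cultures: ES cells, embryoid bodies at day 6 and N2B27 medium at day 6. The group and the line of each library were taken from its title. Each WT group holds 2 lines, named Ctr (here replicate 1) and WT (replicate 2), and each KO group holds 3 lines, here replicates 1 to 3. Per the labels' protocols, RNA was extracted with Trizol, mRNA was selected with oligo(dT) beads and fragmented, and first strand cDNA was made from random hexamers. Nothing in the labels states that the same named line in different cultures was grown on separate occasions, so the p-values measure the spread between these libraries, which may be partly technical.

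The authors deposited 1 table of FPKM values (fragments scaled to transcript length and library size, per the file headers) for 18762 genes with 2 decimals. Bowtie2, RSEM and the mouse genome build mm10 are named in the submitters' processing notes. Their versions, their roles, the annotation and any filter were not given in the sources used here. RSEM shares ambiguous fragments between transcripts by estimation, so the values of near-identical copies of a gene depend on that estimate. In the table, 27 gene symbols had been turned into dates by a spreadsheet program and were restored through their Entrez IDs, and 2 genes had no symbol. Of the IDs, 18717 matched the RefSeq annotation of GRCm38.p6, from which coordinates were taken. Transcripts and their exons were taken from the GENCODE annotation of the same assembly. In all libraries, 210 genes were listed at 0, and no mitochondrially encoded gene was in the table.

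The number of fragments per library was not given in the sources used here. It was estimated from the low values of the table, where the value of a gene with a single transcript is a whole multiple of the value of 1 fragment if whole fragments were counted. The totals at which the largest share of these values was whole, within a tolerance of 0.1 fragments, were 16100000 to 18300000 fragments per library. At those totals, 40.4% to 61.5% of the 53 to 106 values used per library came out whole, against a median of 17.9% to 19.8% over totals tried from 5000000 to at least 19500000. At this estimated depth 1 fragment on a transcript of 1 kb corresponds to an FPKM of 0.0546 to 0.0621. No confidence interval was computed, because the estimate rests on the rounding of the table. A count test was not run, since the values are not counts.

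Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, the group means of all 15 libraries in 1 fit (9 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 12929 genes. There were 10 contrasts: KO against WT in each of the 3 cultures, each culture at day 6 against ES cells in each genotype, the genotype difference in both of these changes (the interaction), and KO against WT over the mean of the 3 cultures of each line (5 line means, 3 residual degrees of freedom). All adjusted p-values of genes in the text come from this limma test.

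Gene lists were tested with camera in limma with a preset correlation of 0.01, and again with the correlation between members estimated from the residuals. The Benjamini-Hochberg adjustment was over the 38 lists of a contrast. Of the 40 lists fixed before the data were examined, these 38 had at least 5 measured members: naive pluripotency, core pluripotency, formative and primed pluripotency, two-cell-like genes, primitive streak and mesendoderm, mesoderm and cardiac, blood and endothelium, endoderm and extraembryonic endoderm, trophoblast, neural progenitor, neuron, glia, neural crest, surface and simple epithelium, fibroblast and feeder cells, Hox genes, MYC targets, cytosolic ribosomal proteins, ribosome biogenesis, RNA m6A machinery, translation factors, ATF4 and integrated stress response, unfolded protein response, p53 targets, FGF and ERK response, BMP and SMAD1 response, Nodal and SMAD2 response, WNT response, Notch response, hypoxia and glycolysis, oxidative phosphorylation, cell cycle S phase, cell cycle G2 and M phase, replication-dependent histones, imprinted genes, germline genes, cholesterol synthesis and interferon response. The list of mitochondrially encoded genes (0 measured members) and that of Y-linked genes (4) were not tested.

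The genes named in the text follow a rule that was also fixed before the data were examined, together with the design and the alternatives. It names 22 genes always, and in each contrast up to 10 genes per direction with the largest log2 fold change among those with an adjusted p under 0.05, a mean FPKM of at least 5 in 1 of the compared groups and no overlap between the libraries compared. Predicted or unnamed symbols were counted but not named. Where no gene passed, the 5 with the smallest p were named. Of each list up to 4 members were named, those with the largest significant change, or the 2 with the highest mean where none passed. A gene named outside this rule is said to be so where it appears. Some genes that fall under the rule are counted but not reported here by name.

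The same line name occurs in all 3 cultures, and libraries of one name were taken as one line, so that the names pair the libraries. The labels do not state that a name marks one culture lineage. The pairing was checked with the correlation of deviations from the group means: over 15 pairs of libraries of the same line it ranged from -0.18 to 0.27, and 3 pairs were over 0.1. In WT the deviations of both lines mirror each other, so the WT pairs are not independent. With the line as a random block, statmod 1.5.0 and limma gave a consensus correlation of -0.0059. The reported values come from the fit without the block, and the fits with the line as a block are among the alternatives.

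The alternatives were a pseudocount of 0.1, no filter (18552 genes) or an FPKM of at least 5 in at least 2 libraries (9865 genes), rescaling of each library to the same sum (TPM) or by median ratios, limma without the trend, a fit on the compared groups only, the line as a block, and leaving out each library in turn. A further one was chosen after seeing the data: both embryoid body libraries with the highest mean of the hypoxia and glycolysis list were left out. It leaves a single WT embryoid body library, so no count of genes is given for it. A contrast of the KO effect in embryoid bodies with that in N2B27 was also added after seeing the data.

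The tests were tested on simulated data, in which 200 of 12929 genes were given known changes in each of 10 simulations per contrast. These 200 were drawn only from genes with a mean FPKM of at least 5 over all libraries. The shares recovered therefore do not cover genes with lower means, such as Hand1 and Kdr. For KO against WT in ES cells, 63.6% of genes changed by 0.5 on the log2 scale, 98.1% of those changed by 1 and 100% of those changed by 2 were recovered, and 6% of calls were false. In embryoid bodies the shares were 67.6%, 98.5% and 99.7% with 4.6% false, and in N2B27 67.3%, 98.2% and 100% with 5% false. For the genotype difference in the change to embryoid bodies they were 23%, 89.1% and 99.2% with 6% false. A shift of the mesoderm and cardiac list by -0.5 was called in 10 of 10 simulations of each contrast. The noise was drawn independently for each gene and library, with the same spread of a gene in all groups. Correlation between genes, unequal spread of the groups and differences between lines were therefore not simulated. The shares do not show how the tests behave where these are present. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.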

Results

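Messenger RNA was profiled in mouse ES cells that were wild type or lacked Mettl5, to find how the transcriptomes of both genotypes differ before and after differentiation. METTL5 is a methyltransferase that places N6-methyladenosine (m6A) on ribosomal RNA of the small subunit, with TRMT112 as its cofactor. The cells were sampled as ES cells (day 0), as embryoid bodies (EBs, aggregates grown without LIF on coated dishes that prevent attachment) at day 6, and in N2B27 medium, used for neural differentiation, at day 6. Each culture had 2 WT and 3 KO libraries, 15 in all. The FPKM of a library summed to 451651 (KO N2B27 replicate 3) up to 554986 (KO EB replicate 1), and 10953 to 11807 genes reached an FPKM of 1. The depth was estimated at 16100000 to 18300000 fragments per library, with totals above those tried not excluded. Libraries of one group correlated with r = 0.9857 to 0.9967 across genes, which are not independent replicates, and no library was a copy of another.

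Mettl5, the targeted gene, was lower in every KO library than in each WT library of the same culture. Mettl5 (Entrez gene 75422) lies on chromosome 2, positions 69871195 to 69886634 of GRCm38, and its protein-coding transcript has 7 exons. Which part was deleted was not given in the sources used here, and the remaining transcript was still detected in each KO library. In ES cells the WT libraries had 20.85 and 19.03 FPKM and the KO libraries 10.65, 7.21 and 9.1. In EBs Mettl5 was 17.7 and 19.79 FPKM in WT and 9.07, 5.22 and 5.41 in KO, and in N2B27 8.37 and 8.65 in WT and 3.91, 6.41 and 3.29 in KO. The log2 difference was -1.08 ± 0.23 (SE) in ES cells (adjusted p = 0.675), -1.42 ± 0.23 in EBs (adjusted p = 0.00576) and -0.82 ± 0.23 in N2B27 (adjusted p = 0.204). Over line means it was -1.11 ± 0.09 (adjusted p = 0.00835). Without WT EB replicate 2 the EB difference of Mettl5 was -1.34 (adjusted p = 0.0895). Without KO N2B27 replicate 2 the N2B27 difference was -1.05 (adjusted p = 0.0217), and without WT line 2 that over line means was -1.09 (adjusted p = 0.0645). The adjusted p of Mettl5 was 0.106 in EBs when only the EB libraries were fitted and 0.0993 over line means without a filter.

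**Figure D1:**
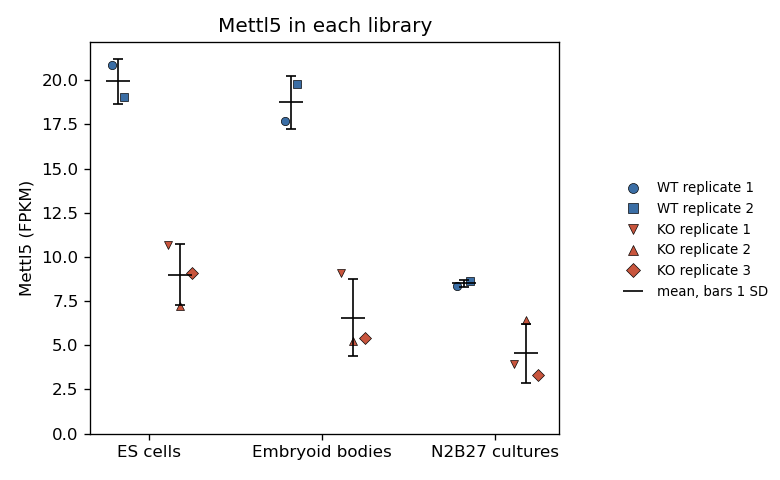
Mettl5 expression in FPKM (linear axis) in ES cells, EBs and N2B27 cultures, with 1 point per library and bars for the mean ± 1 SD of 2 WT or 3 KO libraries. The KO libraries lie at 7.21 to 10.65 FPKM in ES cells against 19.03 and 20.85 in WT, and below both WT libraries in each of the other cultures.

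The change from ES cells to EBs in WT cells gives the background on which the genotypes are compared. Genes of naive pluripotency fell while genes of the primed state, the germ layers and epithelium rose. Klf4, a naive pluripotency transcription factor, fell from 153 ± 2.55 to 7.68 ± 0.255 FPKM (SD, n = 2 each; log2 -4.15 ± 0.15, SE; adjusted p = 1.5e-10), and Esrrb fell from 189 to 22.7 FPKM (log2 -3.01 ± 0.14). Pou5f1 (Oct4), Nanog and Sox2, of the core pluripotency circuit, fell by 1.5 ± 0.26, 1.10 ± 0.25 and 0.94 ± 0.11 on the log2 scale and were still at 348, 177 and 148 FPKM. In total 4633 genes rose and 3050 fell, of which 1442 and 604 changed at least 2-fold. Median-ratio scaling gave 3907 genes higher and 3957 lower, so that 49.7% of calls were higher against 60.3% as reported. Of 20 naive pluripotency genes 19 fell and 1, Dppa3, rose (log2 3.38 ± 0.22; list adjusted p = 7.75e-12, and adjusted p = 0.0678 with an estimated correlation). Of 18 core pluripotency genes 15 fell, such as Dppa2 (log2 -2.67 ± 0.18) and Utf1 (-1.91 ± 0.14), and 1 rose (adjusted p = 1.21e-06, and 0.401 with an estimated correlation). These counts were the same when adjusted over the list alone.

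Primed and germ layer genes rose in WT EBs. Fgf5, a marker of the primed state, rose from 0.175 ± 0.106 to 40.6 ± 0.41 FPKM (log2 5.15 ± 0.23). Of the formative and primed list 13 of 16 genes rose and 3 fell, among them Tcf15 (-3.75 ± 0.17; list adjusted p = 0.000523, and 0.373 with an estimated correlation). T (Brachyury), the primitive streak transcription factor, rose to 61.2 and 44.2 FPKM in both libraries (5.46 ± 0.53), and 16 of 20 streak and mesendoderm genes rose, 17 when adjusted over the list alone, with Fgf8, Sp5 and Mixl1 among them (list adjusted p = 0.000523). Of 21 mesoderm and cardiac genes 15 rose, such as Hand1, a heart and extraembryonic mesoderm regulator (0.22 to 16.2 FPKM, 3.82 ± 0.16; list adjusted p = 0.00131). Among 17 blood and endothelium genes 11 rose, 12 over the list alone, with the VEGF receptor Kdr at 2.53 ± 0.18 (list adjusted p = 0.0253). Of 21 endoderm genes 17 rose, with Gata4 at 2.88 ± 0.31, Sox17 at 2.74 ± 0.34 and Gata6 at 2.18 ± 0.25 (0.000842). Neural progenitor genes rose in 23 of 33 cases, with Nes at 2.67 ± 0.14 and Sox1 at 2.01 ± 0.28 (0.000482), while the neuronal tubulin Tubb3 fell from 118 to 21.5 FPKM (-2.46 ± 0.26). Surface epithelium genes rose in 10 of 14 cases, with Krt18 from 5.41 to 148 FPKM (0.000523), and trophoblast in 6 of 9 (7 over the list alone; 0.0167). For these 7 lists the adjusted p with an estimated correlation was 0.401.

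Other groups also moved in WT EBs. Genes of MYC targets and ribosome biogenesis fell: 37 of 59 and 41 of 72 genes fell, 39 and 42 over the list alone (list adjusted p = 3.65e-07 and 2.19e-08), with Rrp9 at -1.18 ± 0.13 and Nol6 at -1.30 ± 0.10. Myc fell by 1.91 ± 0.17 on the log2 scale. Cytosolic ribosomal protein genes rose in 52 of 85 cases and fell in 3, 54 and 3 over the list alone (adjusted p = 0.000948, and 0.641 with an estimated correlation). Cholesterol synthesis genes rose in 20 of 24 cases, 21 over the list alone, with Cyp51 at 1.48 ± 0.11 (0.000173), and interferon response genes in 15 of 20, with B2m at 2.60 ± 0.13 (0.00059). ATF4 and stress response genes fell in 27 of 39 cases (2.18e-07), S phase genes in 23 of 46 (3.77e-05) and translation factors in 18 of 47 (0.0107). Oxidative phosphorylation genes fell in 23 of 78 cases, 22 over the list alone (0.00203). WNT response (15 of 20 genes higher, 16 over the list alone; 0.0103), Notch response (7 of 11; 0.0167), imprinted genes (16 of 29; 0.0167; Igf2 at 4.66 ± 0.44) and fibroblast genes (9 of 17; 0.0299) rose as lists. With an estimated correlation the adjusted p was 0.401 for MYC targets, ribosome biogenesis, cholesterol synthesis, interferon response, ATF4, translation factors, WNT, Notch and imprinted genes, 0.531 for S phase, 0.589 for oxidative phosphorylation and 0.579 for fibroblast genes. The other 15 lists had adjusted p-values of 0.0714 to 0.91, and for the unfolded protein, FGF and ERK and Nodal lists the mean was above 0 while the test pointed down.

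The largest increases in WT EBs by the named-gene rule were Car4, a carbonic anhydrase (1.58 to 155 FPKM, log2 5.92 ± 0.23), T, Fgf8, Arl4c, Tagln, Fgf5, Krt19 and the kinase gene Pim2 (8.80 to 260 FPKM, 4.75 ± 0.23). Defa-rs4, of a family of near-identical defensin-related copies whose values are uncertain, was listed at 0 in both WT ES libraries and had 38.8 ± 2.72 FPKM in EBs (SD, n = 2), and Defa-rs2 had 28.3 ± 0.827 FPKM. The largest decreases were Inhbb, an inhibin and activin subunit (64.8 to 0.11 FPKM, -5.89 ± 0.10), Mras, Klf4, Cobl, Jam2, Tcf15, Laptm5, Msc, Pcolce and Spry4. Fbxw7, which encodes a ubiquitin ligase subunit, fell by 0.36 ± 0.10 on the log2 scale, and Zfp42 (Rex1) fell by 2.65 ± 0.22. Mycn rose by 0.58 ± 0.22 (adjusted p = 0.0355), a call that was lost with the line as a block (0.0533), with median-ratio scaling (0.106) and without any 1 of the 4 libraries (0.072 to 0.135). Pax6 rose by 0.78 ± 0.23, with an adjusted p of 0.0687 without WT ES replicate 2 and 0.0918 without WT EB replicate 2. Trmt112 was 119 and 102 FPKM (adjusted p = 0.15). Afp, the foetal endoderm marker, was at most 0.03 FPKM in each library and was not tested.

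In N2B27 medium WT cells lost pluripotency gene expression further and gained neural genes. Zfp42 fell from 498 ± 11.1 to 3.03 ± 0.962 FPKM (SD, n = 2 each; log2 -6.97 ± 0.22, SE), Pou5f1 from 990 to 63.1 FPKM (-3.99 ± 0.26) and Nanog from 379 to 13.4 FPKM (-4.75 ± 0.25). Sox1, an early neuroectoderm marker, rose from 6.22 to 124 FPKM (4.11 ± 0.28), Nes, a neural progenitor intermediate filament, from 1.28 to 34.1 (3.94 ± 0.14) and Tubb3 from 118 to 346 (1.54 ± 0.26). Altogether 5367 genes rose and 3775 fell, 2350 and 1195 of them at least 2-fold. Median-ratio scaling gave 4635 higher and 4620 lower, so that 50.1% of calls were higher against 58.7% as reported, and TPM scaling gave 63.6%. All 20 naive pluripotency genes fell (list adjusted p = 1.83e-15, and 0.0281 with an estimated correlation), as did 16 of 18 core pluripotency genes (1.73e-09, and 0.401). Of 33 neural progenitor genes 31 rose, with En1 at 5.77 ± 0.26 and Irx3 at 5.47 ± 0.23 (2.11e-08). In turn 29 of 32 neuron genes rose, with Nefm at 5.13 ± 0.14 and Map2 at 3.46 ± 0.18 (1.46e-06). Notch response genes rose in 9 of 11 cases (Hes5 3.93 ± 0.22; Dll1 4.17 ± 0.28; 0.00516), cholesterol synthesis genes in 23 of 24 (Hmgcs1 43.0 to 258 FPKM; 2.41e-07) and WNT response genes in 14 of 20 (Apcdd1 5.28 ± 0.31; 0.0229). For these 5 lists the adjusted p with an estimated correlation was 0.41.

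Growth-related groups fell in WT N2B27 cultures. Of the ribosome biogenesis genes 60 of 72 fell, 61 over the list alone (list adjusted p = 1.6e-11), of MYC targets 49 of 59, 50 over the list alone (4.39e-10), and of translation factors 29 of 47 (0.000201), each with an adjusted p of 0.41 with an estimated correlation. Ribosomal protein genes fell in 38 of 85 cases, 36 over the list alone (4.98e-06, and 0.569 with an estimated correlation), and oxidative phosphorylation genes in 43 of 78 (4.98e-06, and 0.488). S phase genes fell in 30 of 46 (5.63e-07, and 0.488) and G2 and M phase genes in 28 of 47 (1.95e-05, and 0.476). Germline genes fell in 17 of 24 cases, with the synaptonemal gene Syce1 at -3.61 ± 0.11 (2.3e-06, and 0.401), Nodal response genes in 8 of 12, with Lefty2 at -3.72 ± 0.27 (0.00145, and 0.41), and two-cell-like genes in 9 of 15 (0.00255, and 0.476). Hypoxia and glycolysis genes fell in 12 of 32 cases, with Ldha at -1.91 ± 0.14 (0.024, and 0.708), and histone genes in 10 of 43, 5 over the list alone (0.0474, and 0.41). The p53 target genes rose in 22 of 32 cases, with the cell cycle inhibitor Cdkn1a from 31.3 to 195 FPKM (2.60 ± 0.12; 0.00848, and 0.429). Endoderm genes (13 of 21; 0.0326, and 0.532), formative genes (11 of 16; 0.0326, and 0.41) and imprinted genes (19 of 29; 0.0403, and 0.41) also rose. By the named-gene rule the largest increases were Igfbp5, Ptn, Crabp2, Igf2, Thbs1, Wls, Cdh2, En1 and Tagln, at 5.72 to 7.31 on the log2 scale, and Wnt1, which was listed at 0 in both WT ES libraries and had 69.9 ± 17.4 FPKM in N2B27. The largest decreases were Zfp42, Dppa5a, Tdgf1, Esrrb, Tdh, Tcf15, Utf1, Inhbb, Dppa2 and Bcl3. Fbxw7 rose by 0.41 ± 0.10 and Mettl5 fell by 1.14 ± 0.25 on the log2 scale. The other 15 lists had adjusted p-values of 0.0699 to 0.802, and for blood and endothelium, Hox, m6A, ATF4, FGF and ERK and interferon genes the signs of the mean, the median and the test differed.

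**Figure D2:**
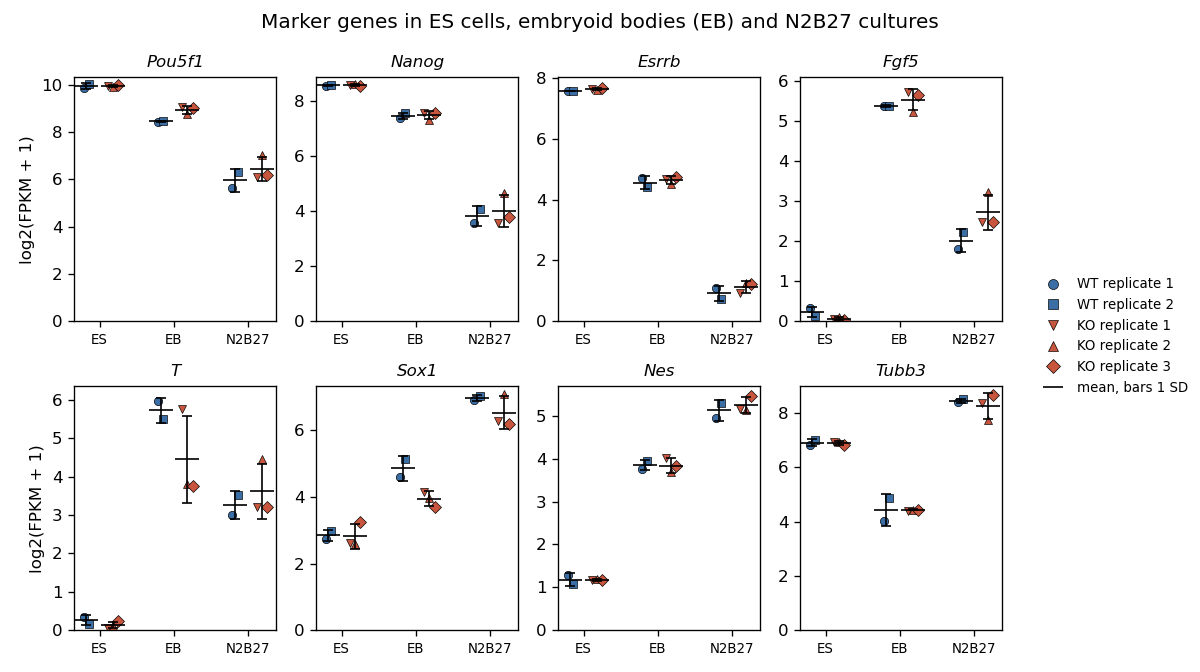
Expression of 8 marker genes as log2(FPKM + 1) in ES cells, EBs and N2B27 cultures, with 1 point per library and the mean ± 1 SD of 2 WT or 3 KO libraries. Pou5f1, Nanog and Esrrb decrease from ES cells to both day 6 cultures in WT and KO, Fgf5 and T have their highest group means in EBs, and Sox1, Nes and Tubb3 in N2B27. For T, KO N2B27 replicate 2 (20.88 FPKM) lies above KO EB replicates 2 and 3 (13.13 and 12.61 FPKM).

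In KO cells the same changes were tested, to compare them with those of WT cells. In EBs 4686 genes rose and 3685 fell in KO cells, and in N2B27 5618 rose and 4288 fell. With TPM scaling the EB counts were 4000 and 4414, so that 47.5% of calls were higher against 56.0% as reported. In N2B27 median-ratio scaling gave 5017 and 4923 (50.5% higher, against 56.7% as reported) and TPM scaling 62.8% higher. In KO EBs 19 of 20 naive pluripotency genes fell (adjusted p = 2.23e-10, and 0.102 with an estimated correlation), Pou5f1 fell from 976 to 493 FPKM (log2 -0.99 ± 0.21), and Fgf5 (5.47 ± 0.18), Car4 (6.05 ± 0.19) and T (4.31 ± 0.44) rose. Of the KO mesoderm and cardiac genes 7 of 21 rose and 3 fell (list adjusted p = 0.191), and of the blood and endothelium genes 11 of 17 rose, 12 over the list alone, and 5 fell (0.224). Hand1 rose to 2.52 ± 0.794 FPKM (SD, n = 3; 1.52 ± 0.13) and Gata4 to 3.07 ± 0.355 FPKM (1.64 ± 0.25). Hypoxia and glycolysis genes rose in 23 of 32 cases, 24 over the list alone (adjusted p = 0.00205, and 0.692 with an estimated correlation). In KO N2B27 cultures all 20 naive pluripotency genes fell (6.75e-14, and 0.0403), 31 of 33 neural progenitor genes rose (1.22e-07, and 0.388), 29 of 32 neuron genes rose (1.77e-05, and 0.422) and all 15 two-cell-like genes fell (7.73e-05, and 0.422). There Sox1 rose to 93.9 ± 34.9 FPKM (3.70 ± 0.23) and Crabp2, a retinoic acid binding protein gene, to 387 FPKM (7.46 ± 0.22), while Dppa5a fell to 4.98 FPKM (-7.63 ± 0.22). Among lists not called in KO the signs of mean, median and test differed for unfolded protein, FGF and ERK, histone and germline genes in EBs and for m6A, ATF4, FGF and ERK and interferon genes in N2B27.

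KO and WT ES cells were compared to find differences present before differentiation. Pluripotency genes were at similar levels: Pou5f1 had 976 ± 23.2 FPKM in KO (SD, n = 3) and 990 ± 90.4 in WT (SD, n = 2), Nanog 382 and 379, and Sox2 315 and 285. Trmt112 had 114 FPKM in KO and 119 in WT, Fbxw7 9.32 and 9.75, and Myc 65.0 and 68.9 (adjusted p = 1 for each of these genes). With limma no gene passed the adjusted threshold, and 447 genes had an unadjusted p under 0.05, where 646 would by chance. The 5 genes with the smallest p all had an adjusted p of 0.675: Arhgap9 (log2 0.72 ± 0.13), Mapt (0.65 ± 0.14), Gja1 (-0.46 ± 0.10), Ap4s1 (-0.45 ± 0.09) and Mettl5. The count of 447 depends on the spread shared over all groups. When only the ES libraries were fitted, 1058 genes had an unadjusted p under 0.05 in limma, and again no gene passed the adjusted threshold. Genes of the two-cell-like state, which marks a small share of ES cells, were higher as a list: 14 of 15 were above WT, 9 of them passed when adjusted over the list alone and none over all genes (list adjusted p = 4.84e-12, and 0.751 with an estimated correlation). Zscan4f, whose reads are shared with its copies, had 37.5 ± 8.59 FPKM in KO and 17.9 ± 14.6 in WT (log2 1.25 ± 0.47, adjusted p = 1). The p53 targets were lower as a list, with 25 of 32 below WT, 1 passing over the list alone and none over all genes, and a mean of -0.084 (adjusted p = 0.00153, and 0.999 with an estimated correlation). Without WT ES replicate 2 both calls ended, with a mean of 0.159 for two-cell-like genes against 0.493 (adjusted p = 0.0536) and of -0.063 for p53 targets (0.361). The other 36 lists had adjusted p-values of 0.112 to 0.999, with signs that differed between mean, median and test for blood, trophoblast, translation factor, Nodal, oxidative phosphorylation and histone genes. Without WT ES replicate 1 4 genes passed, and without WT ES replicate 2 2 genes passed.

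In EBs, genes of mesoderm, heart, blood vessels and endoderm were lower in KO than in WT. Hand1 (Entrez gene 15110, chromosome 11, positions 57828713 to 57832147 of GRCm38) had 2.52 ± 0.794 FPKM in KO (SD, n = 3) and 16.2 ± 0.375 in WT (SD, n = 2). The log2 difference was -2.31 ± 0.14 (SE; adjusted p = 3.1e-06), and Hand1 was lower in 3 of 3 KO libraries. Aplnr, the apelin receptor of early mesoderm, was 1.5 against 8.94 FPKM (-2.10 ± 0.29, adjusted p = 0.00219). Kdr was 1.47 ± 0.232 against 5.23 ± 0.276 FPKM (-1.34 ± 0.17, adjusted p = 0.00111) and Gata4, a cardiac and endoderm transcription factor, 3.07 ± 0.355 against 11.1 ± 3.42 FPKM (-1.54 ± 0.28, adjusted p = 0.0114). The other large decreases were Rspo3, Mesp1, Dkk1, Msx1, Frzb, Cfc1 and Vstm2b, at -1.42 to -1.66 on the log2 scale. All 21 mesoderm and cardiac genes had lower means in KO: 10 passed over all genes and 15 when adjusted over the list alone, Foxf1 (-1.38 ± 0.13) and Hand2 (-1.35 ± 0.12) among them (list adjusted p = 1.64e-16, and 0.0306 with an estimated correlation). All 17 blood and endothelium genes also had lower means, and 5 passed over all genes and 8 over the list alone, such as Lmo2 (-1.40 ± 0.21), Cdh5 (-0.82 ± 0.13) and Fli1 (-0.66 ± 0.11; list adjusted p = 1.76e-07, and 0.0306 with an estimated correlation).

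Endoderm, streak and neural genes were lower in KO EBs as lists. Of 21 endoderm genes 5 passed, 8 over the list alone, with the chemokine receptor Cxcr4 at -1.38 ± 0.20 and Cited1 at -1.05 ± 0.20 (list adjusted p = 8.28e-08, and 0.164 with an estimated correlation). Sox17 (2.64 against 7.37 FPKM, adjusted p = 0.0543) and Gata6 (2.63 against 5.42 FPKM, 0.0717) did not pass. Of 20 streak and mesendoderm genes 18 had lower means, and 2 passed, 11 over the list alone (1.04e-07, and 0.271), with Tbx6 at -0.78 ± 0.17. The mean log2 value of this list was 3.251, 2.219 and 2.301 in KO replicates 1 to 3 and 3.551 and 3.164 in WT. KO EB replicate 1 thus lay within the WT range, and the decrease came from the other KO libraries. T was 53.3, 13.1 and 12.6 FPKM in the KO libraries and 61.2 and 44.2 in WT (adjusted p = 0.229), and Mixl1 6.81 ± 6.19 and 13.3 ± 0.467 (0.169). Of 33 neural progenitor genes 3 passed, 11 over the list alone: En1 (-1.09 ± 0.24), Irx3 (-0.95 ± 0.21) and Cdh6 (-0.91 ± 0.20; 2.12e-06, and 0.271). Sox1 was 14.4 ± 2.37 FPKM in KO and 28.4 ± 7.62 in WT (adjusted p = 0.0859). Neural crest genes (3 of 13, 5 over the list alone, with Snai1 at -0.96 ± 0.23; 0.00517, and 0.271) and Hox genes (2 of 9, 4 over the list alone, with Hoxd9 at -0.82 ± 0.10; 0.00429, and 0.271) were lower. So were trophoblast (2 of 9, 3 over the list alone; 0.0175, and 0.371) and fibroblast genes (2 of 17, 6 over the list alone, with Col1a1 at -0.80 ± 0.17; 0.0435, and 0.69). Imprinted genes were lower too (3 of 29, 4 over the list alone; 0.0335, and 0.287), with Peg3 at -1.0 ± 0.17.

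**Figure D3:**
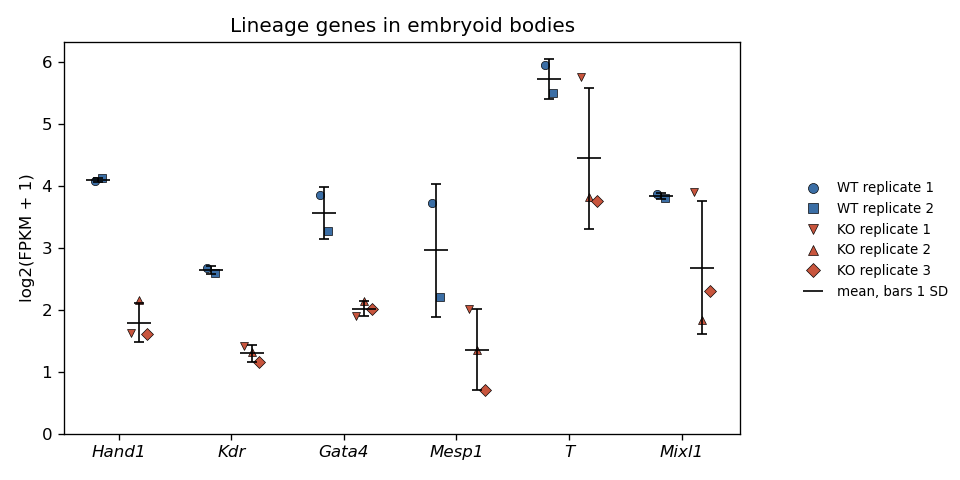
Expression of Hand1, Kdr, Gata4, Mesp1, T and Mixl1 as log2(FPKM + 1) in EBs, with 1 point per library and the mean ± 1 SD of 2 WT or 3 KO libraries. In EBs the KO libraries lie below both WT libraries for Hand1, Kdr, Gata4 and Mesp1, while for T 1 KO library (53.3 FPKM) lies within the WT range of 44.2 to 61.2 FPKM and the others are at 12.6 and 13.1.

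Targets of BMP and WNT signalling were also lower in KO EBs. BMP and SMAD1 response genes passed in 4 of 14 cases, 9 lower and 1 higher over the list alone, with the homeobox gene Msx2 at -1.10 ± 0.23, Tbx3 at -0.77 ± 0.15 and Smad6 at -0.68 ± 0.12 (list adjusted p = 6.96e-05, and 0.0893 with an estimated correlation). WNT response genes passed in 6 of 20 cases, 10 over the list alone, with Dkk1, a secreted WNT antagonist, at -1.61 ± 0.21, Cdx2 at -1.08 ± 0.20 and Sp8 at -0.96 ± 0.17 (3.01e-05, and 0.0893). Nodal and SMAD2 response genes were higher as a list with none of 12 passing (0.016, and 0.478), among them Tdgf1 at 291 against 198 FPKM (adjusted p = 0.305). The Notch list missed the threshold (0.0551), as did FGF and ERK response genes (0.842, with a mean of -0.044 and a test pointing up), although Spred1 passed at -0.40 ± 0.09.

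Two-cell-like genes, some germline genes and a few pluripotency genes were higher in KO EBs. Utf1, a chromatin protein gene of ES cells, was 345 ± 27.7 FPKM in KO (SD, n = 3) and 202 ± 29.9 in WT (SD, n = 2; log2 0.78 ± 0.13, adjusted p = 0.00839), and Dppa2 was 21.8 against 12.8 FPKM (0.69 ± 0.17, adjusted p = 0.0489). These were 2 of 18 core pluripotency genes that passed, also 2 over the list alone (list adjusted p = 0.000112, and 0.336 with an estimated correlation), whereas Pou5f1 had 493 ± 55.1 against 348 ± 4.5 FPKM (adjusted p = 0.344), and Nanog 179 against 177 (0.985). In the naive list, called upward with a mean of 0.049 (0.0388, and 0.431), both members that passed were lower, Dppa3 (11 against 22.5 FPKM, -0.96 ± 0.20) and Tbx3, and 1 was higher over the list alone. Of the formative and primed genes 2 were higher and 1 lower, 5 and 2 over the list alone (0.00294, and 0.164): Tcf15 (0.73 ± 0.16), Grhl2 (0.56 ± 0.14), whose call was lost with the line as a block (adjusted p = 0.0501), and Cdh2 (9.25 against 22.7 FPKM, -1.24 ± 0.17). Germline genes were higher in 4 of 24 cases, 8 over the list alone (1.31e-06, and 0.151), with Mael at 1.08 ± 0.17, Ddx4 at 0.82 ± 0.15, Syce1 at 0.79 ± 0.10 and Slc25a31 at 0.57 ± 0.13. Of 15 two-cell-like genes 5 were higher, 13 over the list alone (5.38e-16, and 0.0893). Zscan4b, Zscan4c and Zscan4d had 10.2 to 14.9 FPKM in KO and 2.63 to 4.01 in WT (1.61 to 1.66 on the log2 scale), and Usp17le was at 1.06 ± 0.22, but the copies of these families share fragments, so single members are uncertain. Further increases were Ccno, Tmem54, Stra8, Cdk5r2 and Abcc4, at 0.88 to 1.10 on the log2 scale.

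Among groups of growth and stress genes few members passed in KO EBs. Ribosomal protein genes were higher as a list, with 82 of 85 above WT, a mean of 0.14 and none passing (list adjusted p = 3.67e-14, and 0.371 with an estimated correlation). Rps26, the most abundant of those named, had 6638 ± 297 FPKM in KO (SD, n = 3) and 5835 ± 317 in WT (SD, n = 2; adjusted p = 0.574). Histone genes were higher as a list with none of 43 passing (0.00364, and 0.0893), and ATF4 and stress response genes with 1 of 39, also 1 over the list alone, the arginine transporter gene Slc7a3 (0.57 ± 0.13; 0.00187, and 0.438). The ATF4 call ended, and its mean went from 0.094 to -0.022 and -0.009, without WT EB replicate 2 and KO EB replicate 2. Of the m6A machinery 1 of 23 genes passed, 2 over the list alone, Igf2bp3 at -0.28 ± 0.06 (list adjusted p = 0.351), and Trmt112 had 103 FPKM in KO and 102 in WT. Fbxw7 (6.35 against 7.35 FPKM, adjusted p = 0.37) and Myc (15.6 against 17.6 FPKM, 0.622) did not pass. Not called were translation factors (0.189), ribosome biogenesis (0.539), MYC targets (0.789), the unfolded protein response (0.296), p53 targets (0.167), oxidative phosphorylation (0.208), S phase (0.939), G2 and M phase (0.0678), cholesterol synthesis (0.0808) and interferon response (0.332). The neuron list (0.132) held 1 gene that passed, Nefl (0.70 ± 0.14), the glia list (0.998) 1, Pdgfra (-1.24 ± 0.23), and surface epithelium (0.185) none. For the neuron, glia, MYC, ribosome biogenesis, translation factor, oxidative phosphorylation and interferon lists the mean, the median and the direction of the test were not of 1 sign.

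Oxygen-related genes set 2 EB libraries apart in a way that crossed the genotypes. The mean log2 value of the hypoxia and glycolysis list was 6.71 in WT EB replicate 1 and 7.15 in KO EB replicate 2, against 5.92 in WT EB replicate 2, 6.08 in KO EB replicate 1 and 6.41 in KO EB replicate 3. Adm, a hypoxia-induced peptide hormone gene, had 9.98 and 25.1 FPKM in the first pair and 1.32, 2.82 and 5.05 FPKM in the other libraries. As a list these genes were called higher in KO EBs, with 30 of 32 above WT, none passing and a mean of 0.236 (adjusted p = 2.04e-05, and 0.546 with an estimated correlation). The mean was -0.156 without WT EB replicate 2 and 0.627 without WT EB replicate 1. Leaving out both high libraries, an alternative chosen after seeing the data, leaves a single WT EB library. That fit holds no spread within WT EBs, so it cannot show whether the difference between KO and WT EBs holds apart from these genes.

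**Figure D4:**
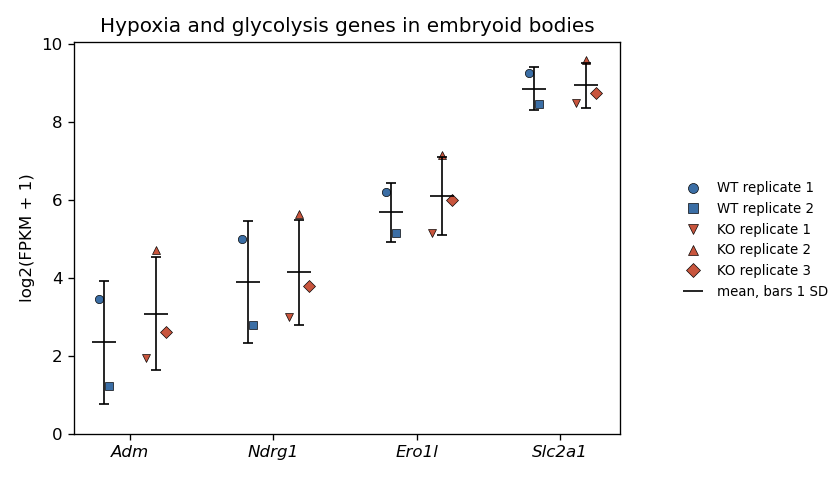
Expression of Adm, Ndrg1, Ero1l and Slc2a1 as log2(FPKM + 1) in EBs, with 1 point per library and the mean ± 1 SD of 2 WT or 3 KO libraries. For Slc2a1, a glucose transporter gene, WT replicate 1 (604 FPKM) and KO replicate 2 (769.8 FPKM) lie above the other 3 libraries, which have 349.7 to 424 FPKM.

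Between KO and WT EBs 84 genes were higher and 209 lower in all, 16 and 49 of them at least 2-fold, and 1895 genes had an unadjusted p under 0.05. Of the 293, 290 had values of their own, the others sharing all values with a copy. The count was 56 without WT EB replicate 2, 74 without KO EB replicate 3 and 160 without WT EB replicate 1, 181 with a pseudocount of 0.1, 156 with the stricter filter and 19 when only the EB libraries were fitted. Median-ratio scaling gave 106 higher and 148 lower (41.7% higher, against 28.7% as reported) and TPM scaling 52 and 226 (18.7%). Of 64 calls on named genes 36 were lost without WT EB replicate 1, 46 without WT EB replicate 2, 40 without KO EB replicate 3, and 8 each without KO EB replicate 1 or 2. The 13 kept in every case were Hand1, Aplnr, Dkk1, Frzb, Vstm2b, Mael, Cdh2, Foxf1, Hand2, Kdr, Cxcr4, Hoxd9 and Syce1, and Hand1, Foxf1, Hand2 and Kdr also passed under each other alternative. Of 22 lists called 14 were kept with each library left out, while 6 were lost without WT EB replicate 2, 4 without KO EB replicate 1, 3 each without KO EB replicate 3 and WT EB replicate 1, and 2 without KO EB replicate 2. These were the ATF4, Nodal, fibroblast, formative, hypoxia, imprinted, naive and trophoblast lists. Without WT EB replicate 2 the mean was -0.383 instead of -0.612 for blood and endothelium and -0.289 instead of -0.474 for neural progenitor genes.

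In N2B27 cultures few genes differed between KO and WT. Ube2ql1, a ubiquitin-conjugating enzyme-like gene, had 19.3 ± 5.14 FPKM in KO (SD, n = 3) and 6.96 ± 1.3 in WT (SD, n = 2; log2 1.33 ± 0.18, SE; adjusted p = 0.0125). Fhl1, a LIM domain protein gene on chromosome X (positions 56731209 to 56793346), had 43.6 ± 2.7 FPKM in KO and 77.8 ± 6.12 in WT (-0.82 ± 0.10, adjusted p = 0.00995). Tex15 (1.08 ± 0.18), Emc8-1190005i06rik (1.04 ± 0.13), Cenpf (0.75 ± 0.12) and Ror1 (0.64 ± 0.09) were also higher, and Gpx3 (-0.84 ± 0.14) and Prrx1 (-0.62 ± 0.11) lower. In all 6 genes were higher and 7 lower, and 1144 had an unadjusted p under 0.05. None was among the genes changed the same way in EBs, where 0.04 higher and 0.11 lower would be shared by chance. In each direction 1 gene went the opposite way: Ror1, lower in EBs (-0.57), and Dmrtb1, higher in EBs (0.69) and lower in N2B27 (-0.74), both named after their values were seen. Gata4 was 2.92 ± 1.62 FPKM in KO and 9.2 ± 3.04 in WT (-1.43 ± 0.28, adjusted p = 0.0768), Sox1 93.9 ± 34.9 and 124 ± 8.03 (0.674), Tubb3 314 and 346 (0.907), and Pou5f1 89.5 ± 34.8 and 63.1 ± 21.5 (0.596). The count of 13 was 0 without KO N2B27 replicate 1, 1 without WT N2B27 replicate 1, 41 without WT N2B27 replicate 2 or KO N2B27 replicate 3 and 249 without KO N2B27 replicate 2. It was 7 with a pseudocount of 0.1, 52 without a filter, and 4 with the stricter filter. Scaling gave 3 with TPM (66.7% higher, against 46.2% as reported) and 8 with median ratios (75% higher). No gene passed when only the N2B27 libraries were fitted, where 902 genes had an unadjusted p under 0.05 in limma. Of the 9 genes that passed under the named-gene rule 9 were lost without KO N2B27 replicate 1, 8 without WT N2B27 replicate 1, 3 without WT N2B27 replicate 2 and 2 without KO N2B27 replicate 3.

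As lists, p53 targets, neuron genes and endoderm genes were lower in KO N2B27 cultures, although no member passed over all genes. Of the p53 targets 30 of 32 were below WT, 8 passing over the list alone, with a mean of -0.277 (adjusted p = 7.07e-14, and 0.142 with an estimated correlation), and Bax, a mediator of apoptosis, had 141 against 161 FPKM (adjusted p = 0.65). Of the neuron genes 30 of 32 were below WT, 6 passing over the list alone (1.74e-09, and 0.613). Their mean was -0.296, and -0.176 without KO N2B27 replicate 2 (adjusted p = 0.000816). Likewise of the endoderm genes 20 of 21 were below WT, 7 lower and 1 higher over the list alone (1.83e-07, and 0.613), with a mean of -0.466, and -0.287 without WT N2B27 replicate 2. Neural progenitor (25 of 33 below WT, 4 over the list alone; 0.00366, and 0.787), germline (20 of 24, 2 over the list alone; 0.00242, and 0.613) and ribosome biogenesis genes (61 of 72; 0.00236, and 0.787) were also lower. Lower as well were MYC targets (45 of 59; 0.0395, and 0.888) and cholesterol synthesis genes (17 of 24; 0.0442, and 0.787). Interferon response (19 of 20 above WT; 0.00243, and 0.613), surface epithelium (10 of 14; 0.00243, and 0.787) and neural crest genes (9 of 13, 1 over the list alone; 0.0395, and 0.613) were higher. The means were -0.068 for MYC targets and 0.246 for surface epithelium, and that of surface epithelium was -0.041 without WT N2B27 replicate 1. The other 27 lists had adjusted p-values of 0.0507 to 0.983, and for ATF4 and hypoxia genes the mean was below 0 while the test pointed up. Of the 11 lists called, those of p53 targets, neuron and endoderm were kept with each library left out. Of the 11, 6 were lost without WT N2B27 replicate 1, 4 without KO N2B27 replicate 3, 3 without KO N2B27 replicate 2 and 2 each without the other libraries.

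**Figure D5:**
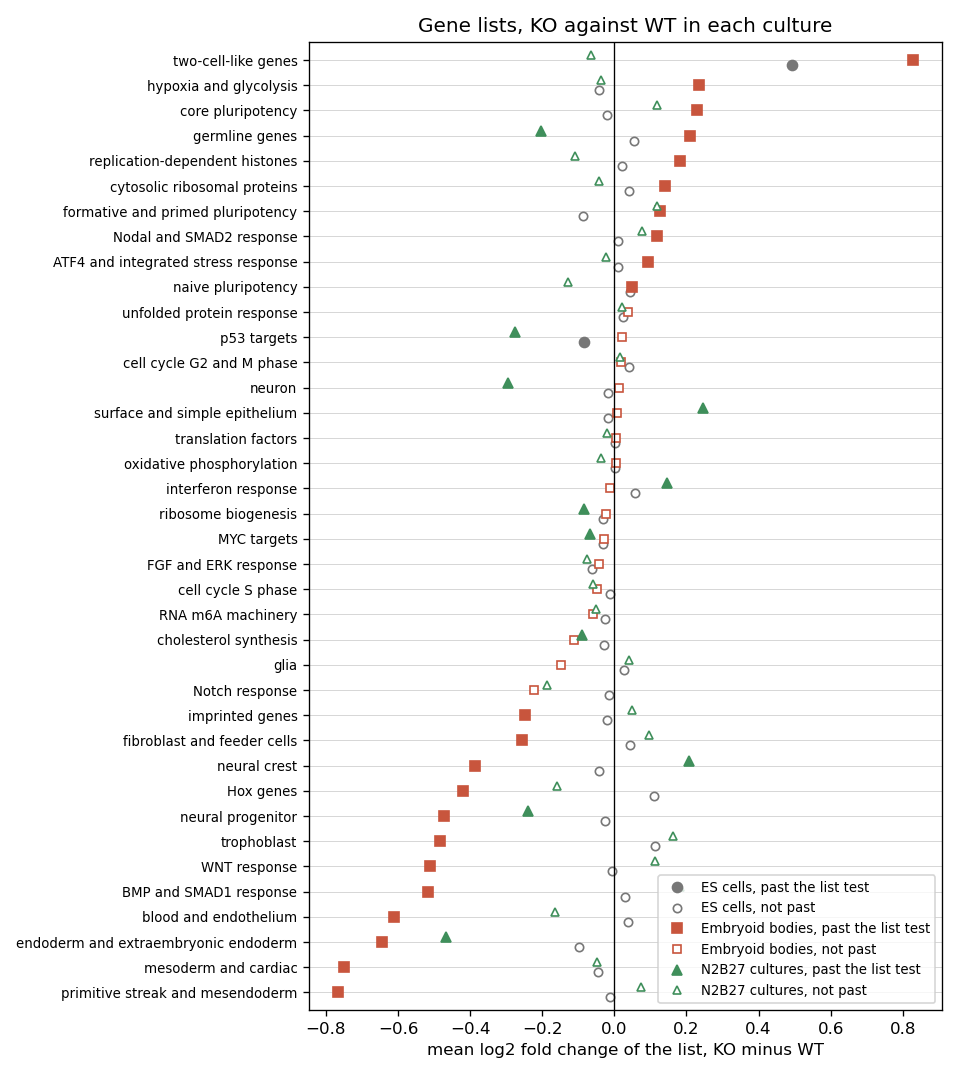
Mean log2 fold change, KO minus WT, of the 38 tested gene lists in ES cells, EBs and N2B27 cultures, with filled points for lists called with the preset correlation. The mesoderm and cardiac list lies at -0.75 in EBs and at -0.045 and -0.047 in ES cells and N2B27, and the two-cell-like list at 0.829 in EBs and 0.493 in ES cells.

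Whether the change from ES cells to EBs differed between the genotypes was tested as an interaction. Hand1 rose less in KO than in WT, with a difference between the changes of -2.29 ± 0.20 on the log2 scale (adjusted p = 0.000306). Foxf1 (-1.40) and Hand2 (-1.34), both with an adjusted p of 0.00585, Kdr (-1.34, adjusted p = 0.0415), Cdh5 (-0.99, 0.0495), Zfpm1 (-1.32, 0.0456) and Tbx20 (-0.76, 0.0353), genes of heart, vessel and blood development, had lower changes as well, as did Vstm2b, Asb4 and Greb1 (each 0.0211). Syce1 (0.89, 0.0211) and Ccno (1.49, 0.0325) had a higher change in KO. In all 2 genes had a higher and 18 a lower change, and 991 had an unadjusted p under 0.05. Of the mesoderm and cardiac genes 4 of 21 passed, 9 over the list alone (list adjusted p = 1.16e-13, and 0.0553 with an estimated correlation), and of blood and endothelium genes 2 of 17, 5 over the list alone (7.47e-07, and 0.0553). All 9 Hox genes had a lower change, 5 over the list alone (5.04e-05, and 0.135), and WNT (4.77e-05, and 0.115) and BMP response genes (8.31e-05, and 0.115) were called downward with none of 20 and 14 passing, 6 and 5 over the list alone. Streak (1.69e-06), endoderm (4.77e-05), neural progenitor (6.01e-05), trophoblast (0.000752) and fibroblast genes (0.0277) were called downward too, with adjusted p-values of 0.289 to 0.645 with an estimated correlation. Neural crest genes (0.0305) were also called downward, and none of the 21 lists called in this contrast passed with an estimated correlation. Called upward were ribosomal protein (9.15e-08), hypoxia and glycolysis (9.53e-06), formative (6.21e-05), germline (6.36e-05), core pluripotency (0.000106), two-cell-like (0.000115), p53 target (0.000574), ATF4 (0.00446), histone (0.00916) and Nodal response genes (0.0277). With an estimated correlation the adjusted p of the upward lists was 0.115 to 0.528, and Syce1 was their only member to pass. The mean fell from 0.277 to -0.114 for hypoxia and from 0.085 to -0.031 for ATF4 genes without WT EB replicate 2, and to -0.022 and -0.019 without KO EB replicate 2. It fell from 0.101 to 0.011 for ribosomal protein genes without WT ES replicate 2 and from 0.336 to 0.001 for two-cell-like genes without WT ES replicate 1, and each of these calls ended. The Nodal, histone, fibroblast, neural crest, neural progenitor and trophoblast calls were also lost without at least 1 of the libraries. With the line as a block 7 genes passed, all of them among the 20, and the calls of Kdr, Cdh5, Zfpm1, Tbx20, Asb4, Greb1, Syce1 and the neural crest list (adjusted p = 0.0305) were lost. With both hypoxia-high EB libraries left out a single WT EB library remained, and no count is given for these 20 genes. Their number was 69, 37, 3 and 6 without KO EB replicate 1, KO EB replicate 2, WT EB replicate 1 and WT EB replicate 2. It was 6 and 1 without WT ES replicate 1 and 2, and 5 without any of the KO ES libraries. They became 1 with a pseudocount of 0.1 or the stricter filter and 36 without a filter, while median-ratio scaling gave 23.8% higher changes against 10%, and of the named genes Hand1 alone passed under each alternative.

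For the change from ES cells to N2B27 cultures 1 gene differed between the genotypes. Fhl1 rose in both genotypes and rose less in KO, by a difference of -1.02 ± 0.14 (adjusted p = 0.0442), and 620 genes had an unadjusted p under 0.05. Two-cell-like genes (14 of 15 with a lower change; list adjusted p = 1.88e-05), neuron genes (28 of 32; 1.47e-05) and p53 targets (29 of 32; 6.83e-05) were called downward. Each had an adjusted p of 0.687 with an estimated correlation, and none of their members passed, over all genes or over the list alone. Endoderm genes (0.00114, and 0.729), germline genes (0.00161, and 0.687), neural progenitor (0.0473, and 0.937), Hox (0.0473, and 0.778) and ribosomal protein genes (mean -0.084; 0.0473, and 0.949) were called downward as well. Formative and primed (0.00161, and 0.687), surface epithelium (0.00487, and 0.853) and neural crest genes (0.0159, and 0.687) were called upward, with no member passing over all genes. Without KO N2B27 replicate 2 the mean of the neuron genes was -0.158 instead of -0.277, and without WT N2B27 replicate 1 that of surface epithelium was -0.023 instead of 0.264. Apart from neuron, p53 and formative genes, each of these list calls was lost without at least 1 of the libraries. The mean of the ribosomal protein genes was 0.005 without WT ES replicate 1 and 0.002 without WT N2B27 replicate 1. The count was 0 without WT ES replicate 2, any KO ES library, either WT N2B27 library or KO N2B27 replicate 1, 4 without WT ES replicate 1 or KO N2B27 replicate 3, and 32 without KO N2B27 replicate 2.

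Averaged over the cultures, KO lines differed from WT lines in 7 genes. The only one with a higher mean was the predicted gene Gm2016 (0.82 ± 0.11, adjusted p = 0.0449), which falls outside the naming rule and was named after its value was seen. Besides Mettl5 the genes with lower means were the endoderm and mesoderm regulators Sox17 (-0.90 ± 0.08, adjusted p = 0.00835), Hand1 (-0.86 ± 0.08, 0.00895), Gata4 (-1.09 ± 0.13, 0.0301) and Gata6 (-0.60 ± 0.07, 0.0301), and Dkk1 (-0.87 ± 0.10, 0.0209). The test had 3 residual degrees of freedom, and 1494 genes had an unadjusted p under 0.05. Of 21 endoderm genes 3 were lower, 13 over the list alone (list adjusted p = 9.39e-14, and 0.276 with an estimated correlation), and all 15 two-cell-like genes were above WT, 11 over the list alone and none over all genes (9.39e-14, and 0.28). The mesoderm list was lower with 1 of 21 genes passing, 11 over the list alone (6.16e-13, and 0.149). The count of 7 became 1 without WT line 2 or KO line 1, 4 without KO line 3, 24 without WT line 1 and 42 without KO line 2. It was 0 without a filter, 11 with the stricter filter, 12 without the trend and 13 with TPM scaling.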

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

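Of the tests in this part, that of the summed Zscan4 family, the share of ES-like signal over core and formative genes, the comparison of the WT pair's genes with the 7 genes of the line means and the alternative without both hypoxia-high EB libraries were chosen only after the results were seen. A tested difference between the genotypes in the change from ES cells to EBs brought 20 genes here, of which 18 had a lower change in KO. On the log2 scale the differences were -2.29 for Hand1, -1.40 for Foxf1, -1.34 for Hand2, -0.76 for Tbx20 and -1.41 for Prdm6, genes of heart and smooth muscle development. They were -1.34 for Kdr, -1.46 for Nrp1, -0.99 for Cdh5, -1.06 for Stard8, -1.17 for Rgs5 and -1.32 for Zfpm1, genes of vessels and blood. The signalling ligands Bmp2 and Wnt5a had -1.08 and -1.33. The others with a lower change were Vstm2b at -1.57, Asb4 at -1.43, Psca at -1.18, Greb1 at -1.16 and Klhl6 at -0.87, and the change was higher for Ccno at 1.49 and for Syce1 at 0.89. Bmp2, Klhl6, Nrp1, Prdm6, Psca, Rgs5, Stard8 and Wnt5a fall outside the naming rule and are given because they passed this test. With the line as a block only 7 of the 20 genes passed, and most of the genes outside the rule lost their call. The same test for N2B27 cultures brought 1 gene here, Fhl1, at -1.02.

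The first pattern weighed was the lower level of mesoderm and cardiac genes in KO EBs, a mean of -0.75 over 21 genes. Scaling of the libraries moves all genes nearly alike, and the median of all genes was -0.0436, which argues against scaling as the whole cause. The mean less the median of all genes was -0.716 under the weaker of 2 scalings. Rescaling could hardly change that difference, so it adds no separate support. A single EB library was also argued against, since the mean was at most -0.672 with 1 of 5 left out. Cells left undifferentiated in KO EBs would bring their pluripotency transcripts: the share of ES-like signal was 2% at the median of 19 naive genes (quartiles 0.5 and 7.6), against 78.5% of the WT rise lost at the median of 15 mesoderm genes (quartiles 61.3 and 84.5). Over 15 core pluripotency genes, a list called higher in KO EBs, the share was 13.4% at the median (quartiles 1.2 and 23.3), and for the 3 formative genes that fell in WT it was 5.4%, 44.4% and 67.6%. ES-like cells as the whole cause were thus argued against by the naive and core genes, while cells at a later pluripotent stage stay open. The loss of Mettl5 may lower mesoderm gene expression in EBs, as a hypothesis found and tested on the same data. Open are differences between the lines in the number or timing of mesoderm cells, and differences unrelated to genotype, since each genotype rests on 2 or 3 lines.

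The second pattern was the higher level of two-cell-like genes in KO EBs, a mean of 0.829 over 15 genes. Reads shared among the 4 Zscan4 genes in the table should change their sum little, but copies outside the table could change it. The summed FPKM was 27.1 higher in the lowest KO EB library than in the highest WT one (53.04, 82.6 and 110.6 in KO, 17.9 and 25.9 in WT). Members of the sum were already called higher, so it adds no separate support. Outside the Zscan4, Usp17l, Tcstv and Tdpoz families the log2 differences in EBs were smaller. They were 0.643 for Tmem92, 0.528 for Arg2, 0.524 for Sp110, 0.52 for Pramef25, 0.365 for B020004J07Rik and -0.076 for Eif1a. A single KO line was argued against, since the mean was at least 0.712 with 1 of 3 KO libraries left out. In ES cells the WT libraries themselves had sums of 63.2 and 18.1 FPKM, against 64.8, 69.8 and 96.1 in KO. A larger share of cells in the two-cell-like state may underlie the pattern, as a hypothesis, and differences between lines that do not come from the genotype stay open.

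The third pattern was the set of 7 genes that differ between KO and WT lines in the mean over the 3 cultures. The explanation that differences between lines unrelated to genotype give such genes predicts that both WT lines differ as much as a KO and a WT line do. With cultures as replicates the WT lines differed in 4 genes, and the 6 pairs of 1 KO and 1 WT line in a median of 3.5 genes (2 to 8). Pairs of KO lines differed in 0 to 9 genes. The 4 genes of the WT pair were Ddx3y, Uty, Eif2s3y and Cd99, and 0 of them were among the 7 genes of the pattern, so these counts decide nothing about those 7. Since each line has 1 genotype, a genotype effect and differences between the lines cannot be told apart for them. Of the 7, Mettl5, Sox17, Gata6 and Dkk1 were lower in all 9 KO libraries than in both WT libraries of the same culture. The 7 genes were selected for a difference between KO and WT in these same libraries, so this adds no separate support. In ES cells Sox17 and Gata6 were near the floor, at most 0.27 and 0.44 FPKM in any library.

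For 4 counts of genes the samples were split in other ways, and 10 splits are too few for a share under 0.05. KO EBs against KO ES cells gave 8314 genes in a fit on these 6 libraries and at most 0 with another split, and KO N2B27 against KO ES cells gave 10239 and at most 0, each matched by 1 of 10 splits, the real one. KO against WT over line means gave 7 genes and at most 1 otherwise, so that again 1 of 10 splits reached the real count. KO against WT in EBs gave 293 genes, but the split of WT replicate 2 with KO replicates 1 and 3 against WT replicate 1 with KO replicate 2 gave 481, so that 2 of 10 splits reached 293. That split parts the libraries with high hypoxia genes from the others and points to a structure of the samples. Without both of these libraries a single WT EB library remains, so that alternative cannot separate a genotype difference from this structure.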

How the results depend on the processing

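The alternative without both hypoxia-high EB libraries was chosen only after the results were seen. Of 17428 results on named genes under the alternatives 16864 kept their side of the threshold and 535 fell below it (297 of them with 1 library or line left out). A further 29 passed it and 0 reversed. A reversal was counted only where the gene passed in at least 1 of the fits compared. Genes that passed in neither fit count as kept whatever their sign, so the share kept does not measure how stable their direction was. Of 2637 results on called lists 2278 kept their direction and their side of the threshold and 350 fell below it (171 of 175 with an estimated correlation). The other 9 reversed, each with 1 library or line left out. For lists the direction is that of the list test, which compares a list with the other genes. The mean of a list can change sign without a reversal, as for ATF4 genes in EBs (0.094, and -0.022 without WT EB replicate 2). Counts of genes for EBs and N2B27 against ES cells stayed within 1.5 times in both genotypes. The line as a block changed no count by over 1.5 times except the EB genotype difference, where 7 genes passed instead of 20. The named calls lost with the block were Mycn in WT EBs, Grhl2 and 7 genes of the EB genotype difference, and the Notch list in KO EBs and the neural crest list in the EB genotype difference.

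For KO against WT in ES cells the count of 0 genes became 1 without a filter. In EBs the 293 genes became 181 with a pseudocount of 0.1 (170 shared), 156 with the stricter filter and 19 in the fit on the compared groups. The 13 genes in N2B27 became 7 with a pseudocount of 0.1, 52 without a filter, 4 with the stricter filter, 3 with TPM and 8 with median-ratio scaling, and 0 in the fit on the compared groups. The 20 genes of the EB genotype difference became 1 with a pseudocount of 0.1 or the stricter filter, 36 without a filter and 48 without both hypoxia-high libraries (13 shared). The 1 gene of the N2B27 genotype difference became 0 with a pseudocount of 0.1, with median-ratio scaling, without the trend and in the fit on the compared groups, 2 with TPM scaling and 4 without a filter. For line means the 7 genes became 0 without a filter, 11 with the stricter filter, 13 with TPM scaling and 12 without the trend. The fit on the compared groups has fewer libraries and residual degrees of freedom, and takes the spread from those groups alone. In it, genes with an unadjusted p under 0.05 in limma went from 447 to 1058 in ES cells and from 1895 to 1280 in EBs. Fewer degrees of freedom alone thus do not account for both changes, and the counts depend on sharing the spread over all groups. Libraries correlated less within EB groups (r = 0.9857 to 0.9933) than within ES groups (0.9958 to 0.9967). A shared spread does not allow for this, so p-values may be too small in EBs and too large in ES cells. The contrast of 0 genes in ES cells with 293 in EBs may partly come from it. The filters change how many genes share the adjustment. For the pseudocount, scaling and trend the cause was not tested.

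With 1 library (for line means 1 line) left out the counts ranged from 0 to 4 in ES cells (4 without WT replicate 1), from 56 (without WT replicate 2) to 383 (without KO replicate 1) in EBs and from 0 (without KO replicate 1) to 249 (without KO replicate 2) in N2B27. They ranged from 1 (without WT ES replicate 2) to 69 (without KO EB replicate 1) for the EB and from 0 to 32 (without KO N2B27 replicate 2) for the N2B27 genotype difference, and from 1 (without WT line 2) to 42 (without KO line 2) for line means. Where 1 WT library was left out, the lone one was assumed to vary like the other groups.

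Lists whose test changed direction had means between the limits below with 1 library or line left out. Means that changed sign while the test kept its direction are not among them. Examples are hypoxia (0.277 to -0.114) and ATF4 genes (0.085 to -0.031) in the EB genotype difference without WT EB replicate 2. Another is G2 and M phase genes over line means without WT line 2 (0.025 to -0.015). Hypoxia and glycolysis genes ranged from -0.156 to 0.627 for KO against WT EBs (without WT replicate 2 and 1) and from -0.069 to 0.173 for line means (without WT line 2 and 1). Surface epithelium genes ranged from -0.041 to 0.534 in N2B27 and from -0.023 to 0.552 for the N2B27 genotype difference (without WT N2B27 replicate 1 and 2). MYC targets in N2B27 ranged from -0.132 to -0.007 (without KO replicate 2 and 3), with a test that pointed up at the latter. Ribosomal protein genes ranged from -0.173 to 0.005 for the N2B27 genotype difference (without WT ES replicate 2 and 1). Adjusted p-values of the reversed lists were 0.161 to 0.962, and the cause was not tested.

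Median-ratio scaling shifted the median log2 change of all genes by -0.11 in WT EBs, -0.136 in WT N2B27 and -0.106 in KO N2B27, and TPM scaling by 0.115 in KO N2B27, relative to the values reported. Of 205 list results that were not called, 89 were called under at least 1 alternative. At an estimated 16100000 to 18300000 fragments an FPKM of 0.0546 to 0.0621 stands for 1 fragment on 1 kb, so genes near that level, such as Afp, could not be compared. In ES cells 63.6% of simulated changes of 0.5 were recovered against 98.1% of changes of 1. These shares are for genes with a mean FPKM of at least 5 and do not cover genes near that level.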

Other observations

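The contrast of the KO effect in EBs with that in N2B27 was chosen only after the results were seen, and the alternatives without 1 library were planned. The KO effect, KO minus WT on the log2 scale, was lower in EBs than in N2B27 for 44 genes and higher for 13, and 1299 genes had an unadjusted p under 0.05. No list was tested on this contrast, and the genes given here were picked from the 57 after their values were seen. Msx1 was lower in KO than in WT EBs (-1.58) and had a difference of 1.21 in N2B27, and the difference between both effects was -2.79 ± 0.45 (SE; adjusted p = 0.0124). The difference between effects was -1.87 for its relative Msx2 (adjusted p = 0.0249), -2.45 for the WNT agonist gene Rspo3 (0.0258), -2.07 ± 0.20 for Hand1 (0.00106), -1.83 for Kdr (0.00312) and -1.55 for Lmo2 (0.0334). It was -1.56 for Nrp2 (0.0135), -1.43 for Plxna2 (0.00661) and -1.52 for Sema3a (0.0123), and on the other side 1.33 for Lat (0.00106) and 1.435 for Dmrtb1 (0.00204). Of the 13 with a higher effect in EBs, 4 predicted genes share identical values (2.19) and count as 1 measurement.

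Single libraries stood apart from their groups in differentiation genes. In KO EB replicate 1 T had 53.3 FPKM and Mixl1 13.9, within or above the WT values of 61.2 and 44.2 for T and of 13.6 and 12.9 for Mixl1, while KO EB replicates 2 and 3 had 13.1 and 12.6 for T and 2.58 and 3.94 for Mixl1. Hand1, Kdr and Gata4 were nevertheless below both WT libraries there, with Kdr at 1.68 FPKM against 5.42 and 5.03. Igf2, an imprinted growth factor gene, had 55.9 and 56.7 FPKM in WT EBs and 15.1, 31.5 and 14.5 in KO EBs. In KO N2B27 replicate 2 Pou5f1 had 129.6 FPKM and Nanog 24.5, against 47.9 to 78.3 and 10.9 to 15.8 in the other N2B27 libraries. Without that library 249 genes passed between KO and WT N2B27 cultures, 182 higher and 67 lower, against 13 with it. The mean of the naive pluripotency list in that library, 1.615, was below both WT libraries (1.699 and 1.672). Its core pluripotency mean, 4.288, was above those of the other N2B27 libraries (3.82 to 3.95). Its neuron mean, 2.585, was below theirs (2.83 to 3.14), while its neural progenitor mean, 3.221, lay between those of the other KO libraries (3.208 and 3.405). The reason for the low count stays open.

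The lines also differed in genes of the Y chromosome. In ES cells Eif2s3y had 11.5 FPKM in the WT line of replicate 1, 0.21 in that of replicate 2 and 22.9, 32.1 and 28.1 in the KO lines, and Ddx3y had 1.52 in replicate 1 of WT and at most 0.11 in the other lines. Over 20 chromosomes the median difference of an ES library from the mean of the lines was at most 0.053 on the log2 scale, and for 217 genes on chromosome X it was 0.033 and -0.018 in the WT lines. In KO replicate 2 Cd99 had 29.4 FPKM in ES cells against 0.85 to 6.3 in the other lines, and Rnf187 47.5 against 90.4 to 103.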
